A study of Homo sapiens with 8 samples.

How the data were processed

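The data were 8 single-colour Affymetrix arrays of RNA from human CD34+ cells of mobilized peripheral blood, a source of hematopoietic stem and progenitor cells. Per the labels, the cells were treated for 24 h with SR1 at 0, 30, 100, 300 or 1000 nM or with LGC006 at 30, 300 or 1000 nM. Each compound and dose has 1 array. RNA was extracted with RNeasy columns and its integrity was read on a microfluidic instrument, and cRNA was amplified and biotin-labelled with a 3' IVT Express kit, per the labels' protocols.

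The deposited values are probe set intensities on a linear scale, and the authors made them with GCRMA, which corrects background by probe sequence, normalizes quantiles and summarises probes, per the submitters' processing notes. The version of GCRMA, the number of arrays normalized together and any later scaling are not given in the sources used here. The lowest intensity was 4.743 on each of the 8 arrays. Between 33.2% and 34.6% of probe sets sat at this floor, so a fold change that reaches it is a compressed one. The median intensity was 5.37 to 5.48 and the 75th percentile 103.2 to 108.1. Signal above background was judged from an intensity of 31 or more, which 18364 to 18527 probe sets reached on an array. Folds against a lower value are given as at least the fold against 31.

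Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none listed. Symbols were brought up to date by gene number for 40984 probe sets from a RefSeq gene table of assembly GRCh38.p14, used for names alone. Probe sets with several genes were not named. Genes of the Y chromosome, XIST and TSIX (59 probe sets) were left out throughout. A gene was represented by its single-gene probe set with the highest mean, on a scale of log2(value + 1). It was tested if it reached 5 on this scale on at least 2 of the 8 arrays, which left 9777 genes. Of these, 4237 had more than 1 such probe set, and 3763 were measured by a probe set whose name marks possible hybridization to other transcripts.

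The main test was a linear model in limma 3.58.1 under R 4.3.3, with moderated variances that follow the mean intensity. It had 1 intercept shared by both compounds and a dose slope for each. Dose was coded as log2(1 + dose / 30 nM) and scaled so that a slope is the fitted log2 change from 0 to 1000 nM. The error is the scatter of single arrays about these lines, with 5 residual degrees of freedom and 4.14 prior ones. The labels do not say that arrays came from separate cultures or donors, so the p-values measure only the spread between these arrays, which may be technical. The only 0 nM array carries an SR1 label and served as the start for LGC006 too. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and intervals are 95% intervals. A second limma model took the 6 arrays at the 3 doses given with both compounds (30, 300 and 1000 nM), with dose as a block, and had 2 residual degrees of freedom. Differences from the 0 nM array at a given dose rest on 1 array each and carry no test.

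Before the data were examined, 25 gene lists were fixed, with 368 genes of which 234 were tested. They cover AHR targets and the AHR complex, NRF2 targets, stem and progenitor cells, mature blood lineages, cell cycle, stress, inflammatory, interferon, metabolic and adhesion genes. Shifts of a list against the other genes were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, which asks whether the genes of a list move one way on balance. Those p-values were adjusted over the 25 lists. Genes are named by a rule fixed at the same time. It takes all genes past the threshold where there are 30 or fewer, and otherwise the 12 largest rises and 12 largest falls of one sign at each dose. Where fewer than 20 passed, it adds up to that number genes with a fitted change of at least 1 in order of p, as values that did not pass. It also takes each tested AHR target and up to 4 members of each other list with the smallest p for SR1. Genes named outside this rule are marked in the text.

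The models were tested on simulated data with the residual scatter of the 9777 genes and 200 changed genes, in 20 simulations. For the SR1 trend, 58.8% of genes with a true log2 change of 0.5 passed, 91.8% of those with 1 and 99.3% of those with 2. For the LGC006 trend these shares were 59.2%, 91.9% and 99.6%, and for the difference 62.9%, 91.6% and 99.0%. Simulated differences that were equal at the 3 matched doses passed in 64.9%, 94.3% and 99.7% of genes. The simulated scatter was normal and independent between genes. Simulated slopes followed the coded dose, and responses of another shape were not simulated and may be found less often. The shares hold for 200 changed genes. With fewer changed genes the Benjamini-Hochberg threshold is stricter, so the shares do not give the chance of finding a change in these data.

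Alternatives tried were 4 other codings of dose, separate intercepts, each compound alone, median centring, a second quantile normalization, no filter and a filter at a mean of 7, 2 other variance models, other ways to treat several probe sets of a gene, a pseudocount of 16, and leaving out each array. A fit without the 0 nM array was added after seeing the data. RNA quality was followed by the ratio of 3' to 5' signal of the GAPDH and ACTB control probe sets. Figures were drawn with matplotlib 3.10.9.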

Results

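Expression was measured on 8 arrays of CD34+ cells from mobilized peripheral blood after 24 h with SR1 or LGC006. SR1 (StemRegenin 1) is an antagonist of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, and the series concerns AHR antagonists in the expansion of human hematopoietic stem cells. LGC006 is known here only by its code. SR1 was given at 0, 30, 100, 300 and 1000 nM and LGC006 at 30, 300 and 1000 nM, with 1 array each, so no dose had a replicate and the number of arrays limits the precision. The arrays were alike in signal, with a Pearson correlation across the 9777 tested genes of 0.995 to 0.998 between any pair. The ratio of 3' to 5' signal was 1.19 to 1.24 for GAPDH. For ACTB it was 3.11 to 4.95 on 7 arrays and 7.23 on the SR1 100 nM array.

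The first comparison asked which genes followed the dose of SR1. The AHR-responsive genes CYP1B1 and AHRR were among those that fell. CYP1B1, a cytochrome P450 that metabolizes polycyclic aromatic compounds, had a fitted log2 change of −5.84 ± 0.70 (SE, 8 arrays) from 0 to 1000 nM (limma, adjusted p = 0.013). AHRR, the repressor of AHR signalling, had one of −3.94 ± 0.21 (adjusted p = 0.00011). At 1000 nM their intensities of 10.4 and 11.8 lay below 31, the level taken as above background, so CYP1B1 was at least 16.1-fold lower than at 0 nM and AHRR at least 6.0-fold lower. Their fitted changes rest in part on such values. In all, 16 of 9777 genes passed, of which 15 fell and 1 rose. At an unadjusted p under 0.05 there were 1037 genes, where 489 are the average under chance, and 755 of these had a positive slope. Of 100 assignments of arrays to labels, the real one included, 6 gave as many as the 1037. The median log2 value of the tested genes was 8.58 at 0 nM and 8.63 and 8.62 at 300 and 1000 nM of SR1. The median over genes of the log2 difference from 0 nM was smaller, at 0.024 and 0.011. An offset between arrays adds to positive slopes.

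The other genes that fell were PRSS23, CTTNBP2, IL9R, LACC1, FAM171A1, HGD, GNG11, DDIT4, TUBB2A, NCF4, NEK6, ABCC4 and LMNA. PRSS23, a serine protease, had a fitted log2 change of −3.22 ± 0.32 (adjusted p = 0.0049) and was 9.36-fold lower at 1000 nM. CTTNBP2, a cortactin-binding protein, reached −2.25 ± 0.23 and IL9R, the interleukin 9 receptor, −2.15 ± 0.21 (both adjusted p = 0.0049). IL9R has pseudogene copies of closely similar sequence, and its 3 probe sets had slopes of −2.83, −2.15 and −1.59. The remaining 10 genes had fitted changes from −1.24 for LACC1 to −0.48 for LMNA, which encodes the nuclear lamins A and C. NCF4, a subunit of the phagocyte NADPH oxidase, and ABCC4, a drug efflux transporter, lay between them at −0.75 ± 0.09 and −0.63 ± 0.08. TUBB2A, at −0.85 ± 0.12 (adjusted p = 0.047), is nearly identical in sequence to TUBB2B, which did not pass (adjusted p = 0.075). From 100 nM on TUBB2B lay below 31, so that it was at least 1.8-fold lower at 1000 nM than at 0 nM. Next by p after TUBB2B among genes with a fitted change of at least 1 that did not pass, SEMA3C, a semaphorin, had −1.34 ± 0.23 (adjusted p = 0.081). NUDT16 and CCL2 (adjusted p = 0.081 and 0.14) lay below 31 at 1000 nM, each at least 1.4-fold lower than at 0 nM. Of the 16 genes, 8 had other probe sets above the filter, and 14 of 14 such probe sets had the same sign.

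All 16 genes lay on the same side of the 0 nM array at each of the 4 SR1 doses and, except for CYP1B1, farthest from it at 1000 nM. CYP1B1 lay below 31 at both 300 and 1000 nM, which leaves these doses without an order. Across the 15 genes that fell, the median log2 difference from 0 nM was −0.38 at 30 nM, −0.69 at 100 nM, −0.88 at 300 nM and −1.11 at 1000 nM. The lowest dose thus carried a median of 35.7% of the distance measured at 1000 nM, and 300 nM carried 81.2%. CYP1B1 had a difference of −2.29 at 30 nM already. The single gene that rose was VCPIP1, a deubiquitinase, at 0.996 ± 0.15 (adjusted p = 0.0496). It rests on 1 dim probe set, below 31 at 0 nM, and was at least 1.8-fold higher at 1000 nM. Its 3 other probe sets, which did not reach the filter, had slopes of −0.06, −0.10 and 0.06.

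**Figure D1:**
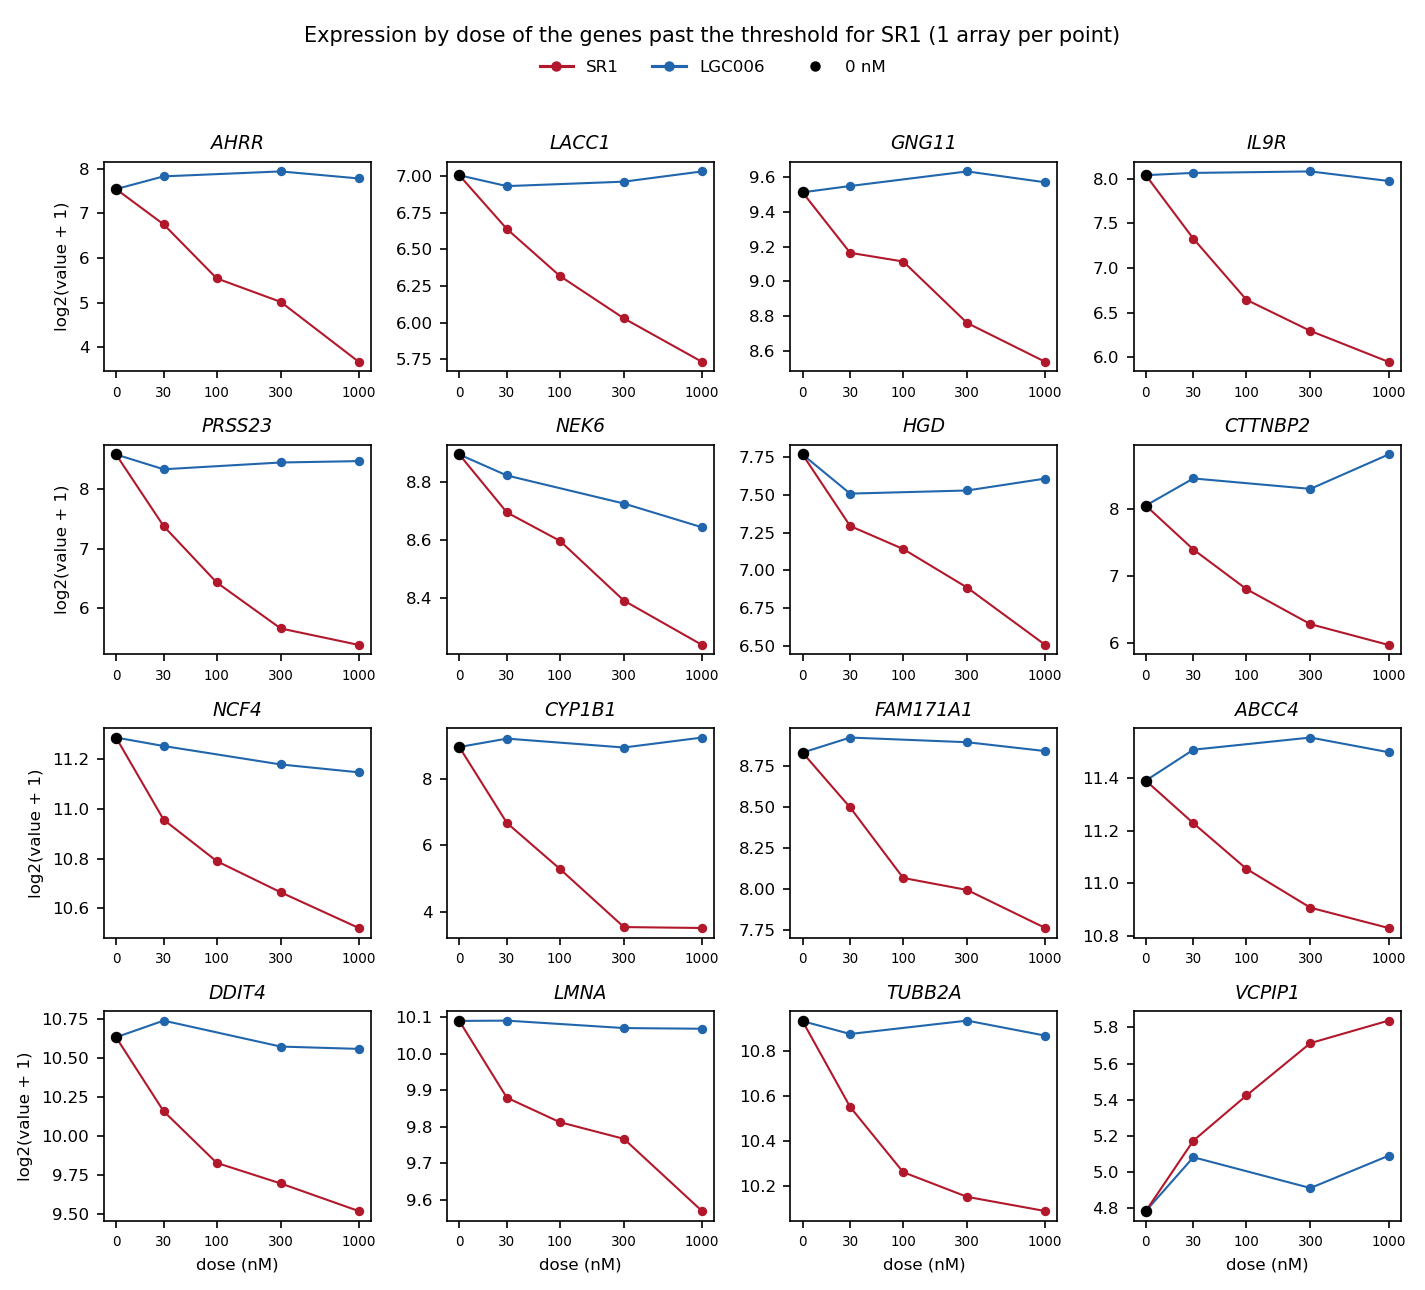
Expression as log2(value + 1) against dose in nM (axis spaced as log2(1 + dose / 30 nM)) for the 16 genes past the threshold for SR1, 1 array per point, SR1 in red, LGC006 in blue and the shared 0 nM array in black. The 15 genes that fell step down with SR1 dose, by a median of −1.11 at 1000 nM, while the median of the LGC006 points at 1000 nM is −0.02.

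These p-values come from scatter about a dose line and depend on its shape. With dose on a linear scale or as a step no gene passed, with a saturating coding 31 did, and with SR1 arrays alone 1 did (AHRR). Without the 0 nM array 3 genes passed, and without the LGC006 30 nM or 300 nM array 8 did.

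Of the 17 listed AHR targets, 9 were tested, of which CYP1B1 and AHRR fell and 7 did not pass. Adjusted over the list alone, 4 fell, the others being EREG and TIPARP. EREG, an epidermal growth factor family ligand, had a fitted change of −0.82 ± 0.17 (adjusted p over all genes 0.13), and TIPARP, a mono-ADP-ribosyltransferase, −0.70 ± 0.17 (adjusted p = 0.18). TIPARP was lower by a similar amount at each dose, with log2 differences of −0.58, −0.66, −0.63 and −0.78. The other 5 had fitted changes of −0.12 ± 0.14 (NQO1), −0.07 ± 0.05 (NFE2L2), 0.05 ± 0.09 (SLC7A5), 0.06 ± 0.11 (HES1) and 0.25 ± 0.27 (PTGS2). The list was shifted down (camera adjusted p = 6.1e-06; adjusted p = 0.27 with an estimated correlation; fry adjusted p = 0.016). With the filter at a mean of 7, which removes CYP1B1, AHRR, EREG, HES1 and PTGS2, the other 4 members had a mean slope of −0.21 where all 9 had −1.24, and the list was not called (adjusted p = 0.072). CYP1A1 and UGT1A6 stood at the floor on all 8 arrays and could not be compared. The single probe set of AHR itself was at the floor on 7 arrays and at 4.752 on the remaining one. CYP1A2, ALDH3A1, STC2, XDH and SCIN did not reach the filter.

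Stem and progenitor markers had mostly positive SR1 slopes, with 17 of 22 tested members above 0 and a median of 0.11. None of the 22 passed over all genes, while adjusted over the list alone 3 rose and 1 fell. CD34, the surface marker by which these cells are selected, had the largest slope at 0.74 ± 0.13 (95% interval 0.44 to 1.03, adjusted p = 0.094). HOPX at 0.44 and ERG at 0.41 came next, and KIT had a slope of −0.16. With single arrays left out the slope was 0.12 to 0.49 for ERG and 0.42 to 0.49 for HOPX. With each array centred on its median the mean slope of the list went from 0.12 to 0.070. Camera did not call the list (adjusted p = 0.17; adjusted p = 0.44 with an estimated correlation), and fry did (adjusted p = 0.016). CD34 passed under the saturating coding of dose (adjusted p = 0.019), and without the 0 nM array its slope was 0.59 (adjusted p = 0.49).

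Megakaryocyte genes and mitosis genes were shifted up under SR1, each with a camera adjusted p = 0.045 and, with an estimated correlation, adjusted p = 0.44. Fry called neither (adjusted p = 0.14 and 0.12). No member of either list passed over all genes. Adjusted over the list alone, 1 of 12 megakaryocyte genes and 3 of 18 mitosis genes rose. The platelet receptor genes ITGA2B and GP1BA had slopes of 0.26 each, and the proliferation genes MKI67 and TOP2A had slopes of 0.41 and 0.35. Both upward shifts lost their call under each other coding of dose and under median centring of the arrays, and without the SR1 1000 nM array or any 1 LGC006 array. Median centring took the mean slope from 0.12 to 0.061 for megakaryocyte genes and from 0.11 to 0.059 for mitosis genes, and the step coding took them to 0.068 and 0.050. Leaving out the SR1 1000 nM or an LGC006 array left them at 0.11 to 0.12. The megakaryocyte list also lost its call without the 0 nM array (mean 0.080) and the mitosis list without the SR1 300 nM array (mean 0.10). The other 22 lists were not called (camera adjusted p from 0.17 to 0.97), and of the 234 listed genes tested, CYP1B1, AHRR and DDIT4 passed. DDIT4, a stress-induced inhibitor of mTORC1 signalling, was 1 of 13 tested genes of the integrated stress and unfolded protein response list, which was not called (camera adjusted p = 0.22), and the other 12 did not pass.

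The second comparison asked the same of LGC006. No gene passed its dose trend in limma (smallest adjusted p = 0.19), and 1100 genes had an unadjusted p under 0.05, a count that 6 of 100 assignments reached. The AHR-responsive genes that fell with SR1 did not pass here, with fitted changes of 0.97 ± 0.68 for CYP1B1 (95% interval −0.58 to 2.51) and 0.36 ± 0.20 for AHRR (−0.10 to 0.82). Their measured log2 differences from 0 nM at 1000 nM of LGC006 were 0.29 and 0.24. Across the 15 genes that fell with SR1, the median difference from 0 nM was 0.03, −0.01 and −0.02 at 30, 300 and 1000 nM of LGC006. At 1000 nM of LGC006, 8 of them lay below 0 nM and 7 above, from −0.25 for NEK6 to 0.77 for CTTNBP2. The genes with a fitted change of at least 1 were FAM131A at 1.02 ± 0.18, KRABD3 at −1.15 ± 0.23, C2orf49-DT at −1.04 ± 0.31 and DIS3L2 at −1.28 ± 0.42 (adjusted p from 0.19 to 0.34), of which the last encodes an exoribonuclease. All but KRABD3 were below 31 on some arrays, so these sizes are uncertain. With single arrays left out they were 0.89 to 1.08 for FAM131A and −1.76 to −0.98 for KRABD3. For C2orf49-DT they were −1.81 to −0.80 and for DIS3L2 −1.59 to −0.59.

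Camera called 4 lists for LGC006 although none of their members passed over all genes. Mitosis genes were shifted up (adjusted p = 0.0070), with MKI67 at 0.40 and TOP2A at 0.47. Neutrophil and promyelocyte genes (adjusted p = 0.011), mast cell, basophil and eosinophil genes (adjusted p = 0.018) and megakaryocyte genes (adjusted p = 0.027) were shifted down. Among them were MS4A3 at −0.19, TPSAB1 at −0.18 and SELP at −0.23, of which the last 2 encode a mast cell tryptase and P-selectin. With an estimated correlation the adjusted p was 0.39 for mitosis and 0.44 for each of the others, and fry called none of the 25 lists. Adjusted over the list alone, 4 of 18 mitosis genes rose, 3 of 13 neutrophil genes and 1 of 7 mast cell genes fell, and no megakaryocyte gene passed. Without the LGC006 1000 nM array no list was called, and the mean slope of the neutrophil list went from −0.11 to 0.00082, that of the mast cell list from −0.10 to −0.15 and that of the megakaryocyte list from −0.096 to −0.12. Without the SR1 30 nM array 2 lists were called. With separate intercepts, and with LGC006 fitted to the 0 nM array alone, 1 list was called up and 0 down. With treated arrays only and separate intercepts, 1 list was called up and 2 down. The downward calls thus varied between fits without the intercept shared with SR1. AHR targets had slopes above 0 in 9 of 9 members, with a mean of 0.25 (camera adjusted p = 0.071). That list was called up with linear dose (0.0068), median centring (0.038), quantile normalization (0.0498), and without the 0 nM (0.015) or LGC006 300 nM array (0.045). Fitted to the 0 nM and LGC006 arrays alone, 6 of 9 slopes were above 0 and the mean was 0.086 (adjusted p = 0.65). The other lists not called ranged up to 0.84.

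The third comparison tested whether the dose trends of SR1 and LGC006 differed, and this was so for 42 genes, 33 lower and 9 higher under SR1. The 16 genes of the SR1 trend were all among them. CYP1B1 differed by −6.80 ± 0.68 (adjusted p = 0.0038), AHRR by −4.30 ± 0.20 (adjusted p = 4.0e-05), PRSS23 by −3.56 ± 0.31 and CTTNBP2 by −3.03 ± 0.22. At 1000 nM the measured intensity of CYP1B1 was at least 19.7-fold lower with SR1 than with LGC006, and that of AHRR at least 7.1-fold lower. IL9R, SEMA3C, SMAD6, LACC1, FAM171A1, DDIT4 and GNG11 followed, from −2.35 to −1.12. TUBB2B also passed and was at least 1.4-fold lower with SR1 at 1000 nM, its SR1 intensity there being below 31. SMAD6, an inhibitor of BMP signalling, had slopes of −0.85 with SR1 and 0.56 with LGC006 and differed by −1.41 ± 0.18 (adjusted p = 0.012). The AHR targets list was shifted down (camera adjusted p = 5.3e-08, and 0.15 with an estimated correlation). Of its 9 members 3 were lower, EREG being the third at −1.06 ± 0.16 (limma adjusted p = 0.036). The measured difference of EREG was 0.11 at 30 nM, −0.40 at 300 nM and −1.30 at 1000 nM.

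The 9 genes higher under SR1 than under LGC006 were LILRA2, DKK1, VCPIP1, FBN1, CRYBG1, ENDOD1, PECAM1, RRAGC and PRDX1. LILRA2, a leukocyte immunoglobulin-like receptor, differed by 1.13 ± 0.18 (adjusted p = 0.039) and DKK1, a secreted WNT inhibitor, by 0.99 ± 0.13 (adjusted p = 0.013). With single arrays left out the difference was 0.69 to 1.31 for LILRA2 and 0.90 to 1.11 for DKK1. PECAM1, an adhesion molecule of endothelial cells, platelets and leukocytes, differed by 0.47 ± 0.08 (adjusted p = 0.046). Its 3 other probe sets above the filter had differences of 0.32, 0.23 and 0.05. With the mean of the probe sets of each gene, PECAM1 at 0.27, ENDOD1 at 0.33 and RRAGC at 0.23 did not pass (adjusted p = 0.21, 0.30 and 0.12). Of the 26 genes called for the difference but not for SR1, 8 had other probe sets above the filter, and 14 of 14 such probe sets had the same sign. The 12 megakaryocyte genes were higher as a list (camera adjusted p = 1.5e-05; adjusted p = 0.18 with an estimated correlation), with 0 passing over all genes and 7 adjusted over the list alone. With treated arrays only and separate intercepts the mean difference went from 0.21 to 0.17 and the list was not called (adjusted p = 0.20). SELP had slopes of 0.26 with SR1 (0.21 to 0.51 with single arrays left out) and −0.23 with LGC006. The stem and progenitor list was not called by camera (adjusted p = 0.33; fry adjusted p = 0.025), with a difference for CD34 of 0.67. The mitosis list had a median difference of −0.01 (camera adjusted p = 0.53). The other lists not called had camera adjusted p-values from 0.065 to 0.76.

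**Figure D2:**
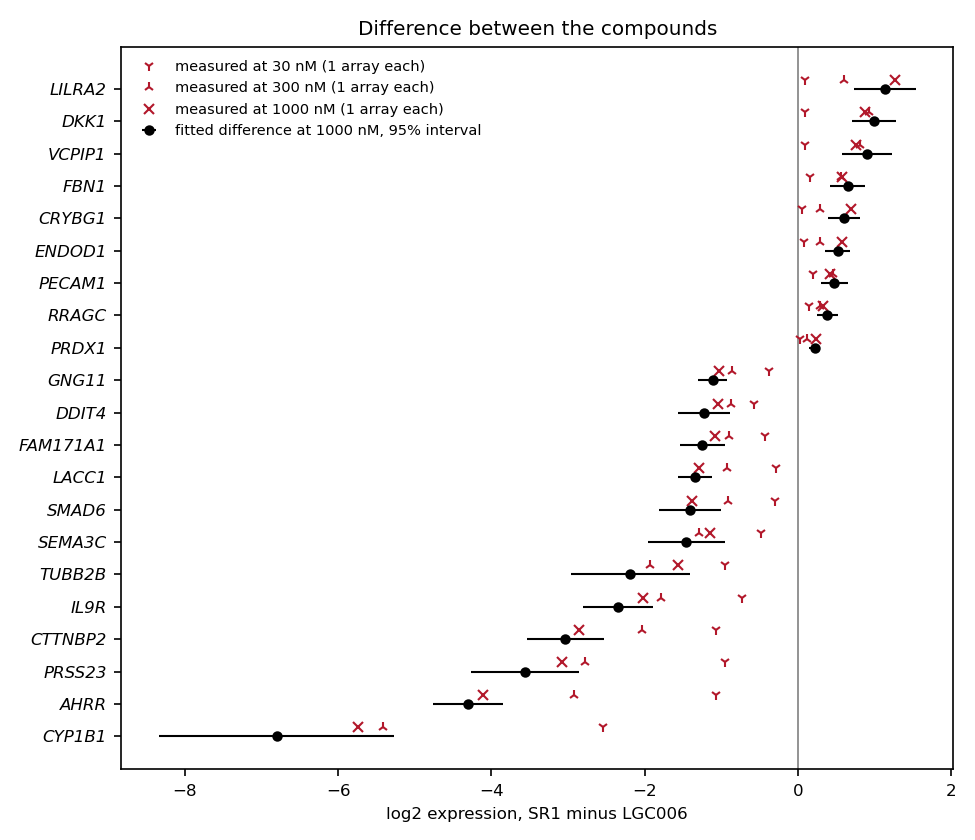
SR1 minus LGC006 in log2 expression for the 21 genes named for the difference, with the fitted difference at 1000 nM and its 95% interval in black and the measured differences at 30, 300 and 1000 nM (1 array of each compound) in red. CYP1B1 is drawn lowest at −6.80 fitted, a size that rests in part on SR1 intensities below 31 (as for AHRR and TUBB2B). LILRA2 is drawn highest at 1.13 fitted and 1.26 measured. That rank depends on 1 array, as its fitted difference was 0.69 to 1.31 with single arrays left out.

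**Figure D3:**
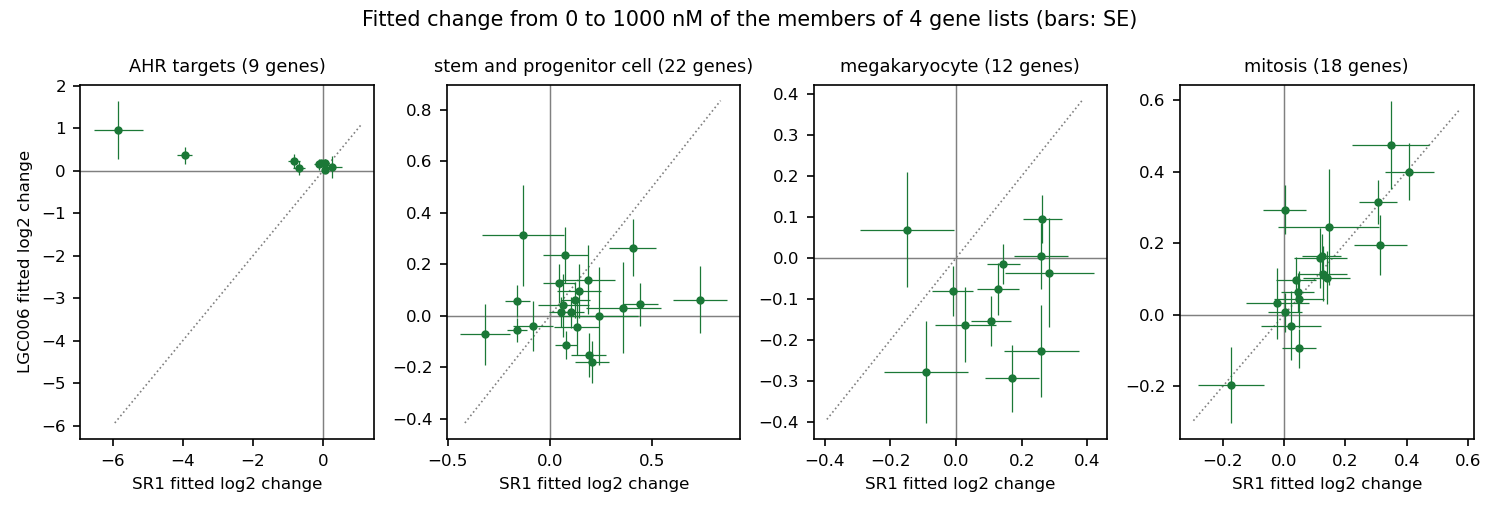
Fitted log2 change from 0 to 1000 nM with LGC006 (vertical axis) against SR1 (horizontal axis) for the tested members of 4 gene lists, 1 point per gene with SE bars and the line of equal change dotted. AHR targets spread to −5.84 along the SR1 axis, 17 of 22 stem and progenitor genes lie above 0 for SR1, megakaryocyte genes lie to the right of the dotted line in 11 of 12 cases, and mitosis genes lie near it.

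For 41 of the 42 genes the measured difference had the same sign at the 3 matched doses, EREG being the exception. Among the 15 genes that fell with SR1, the fitted difference exceeded the measured one at 1000 nM in size for all but HGD. Examples were PRSS23 (−3.56 and −3.08), IL9R (−2.35 and −2.02), DDIT4 (−1.23 and −1.04) and ABCC4 (−0.80 and −0.67). With separate intercepts 1 gene passed and, with the 0 nM array left out as well, 0 did, while leaving out single arrays gave 2 (LGC006 1000 nM) to 31 genes.

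The matched-dose comparison assumed no shape of the dose response, used no 0 nM array and called 2 genes, both lower with SR1. These were U2AF1, a splicing factor subunit, at −1.24 ± 0.07 and ITGAL, the alpha chain of the integrin LFA-1, at −0.95 ± 0.06 (both limma adjusted p = 0.033), named here after their values were seen. Their differences were alike at 30, 300 and 1000 nM, at −1.24, −1.17 and −1.32 for U2AF1 and −0.87, −0.98 and −1.004 for ITGAL. With the mean of the probe sets of each gene the differences were −0.49 for U2AF1 and −0.78 for ITGAL and neither passed (both adjusted p = 0.28). CYP1B1 averaged −4.57 (adjusted p = 0.27) and AHRR −2.70 (adjusted p = 0.39). Both averages rest in part on intensities below 31, and any growth of a difference with dose enters the error of this test. With 2 residual degrees of freedom the count moved between 0 and 4 when single arrays were left out.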

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

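The test of the straight line, the LGC006 part of the test of the SR1 100 nM array, the count of SR1 genes at an unadjusted p, the comparison of mitosis genes with matched random lists and that of the stem cell list were chosen after the results they concern were seen. The results below stand out because the dose slopes of SR1 and LGC006 differed by a test of the difference itself. They are the genes named by the rule and only a part of the 42 called for the difference. Each value is the SR1 slope minus the LGC006 slope on the log2 scale. Negative values were those of CYP1B1 at −6.80, AHRR at −4.30, PRSS23 at −3.56, CTTNBP2 at −3.03, IL9R at −2.35 and TUBB2B at −2.19. SEMA3C at −1.46, SMAD6 at −1.41, LACC1 at −1.35, FAM171A1 at −1.25, DDIT4 at −1.23, GNG11 at −1.12, EREG at −1.06 and HGD at −1.05 were negative too, as were TUBB2A at −0.97, IER3 at −0.90, ABCC4 at −0.80, NCF4 at −0.72, RRM2B at −0.66, LMNA at −0.51 and NEK6 at −0.44. Positive values were those of LILRA2 at 1.13, DKK1 at 0.99, VCPIP1 at 0.90, FBN1 at 0.65, CRYBG1 at 0.60, ENDOD1 at 0.51, PECAM1 at 0.47, RRAGC at 0.38 and PRDX1 at 0.21. The values of CYP1B1, AHRR, TUBB2B, IER3 and VCPIP1 rest in part on intensities below 31 and have no sure size or order. Each group held 1 array, so arrays could not be compared within a group. The residual SD of the main fit was 0.062 (LGC006 1000 nM) to 0.115 (SR1 100 nM), and no array was tested as an outlier.

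Chance assignment of arrays to labels is argued against for the SR1 trend and the difference, under the main coding of dose. With 100 assignments the smallest share possible is 1 of 100. Of 100 assignments of the 8 arrays to the 8 labels, the real one included, 1 gave as many as the 16 genes of the SR1 trend and 1 as many as the 42 of the difference. The highest other assignment gave 14 and 38. It left the 4 SR1 treated arrays at their own labels and gave the other 4 arrays new ones, with LGC006 1000 nM in the place of 0 nM. The count for the difference thus says little about the order of the LGC006 doses. For LGC006, 100 of 100 assignments gave at least its 0 genes (highest other 4), which holds for any assignment and so decides nothing. Chance cannot be excluded for the counts at an unadjusted p under 0.05, where 6 of 100 gave at least the 1100 genes of LGC006 (highest other 1324) and 6 of 100 at least the 1037 of SR1 (highest other 1389). The 10 divisions of the 6 matched arrays are too few for a share under 0.05. The real one gave 2 genes and the highest other 0, and 1 of 10 was as large as the real one.

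Of the 15 genes that fell with SR1, 12 had LGC006 slopes above 0, as if the compounds acted in opposite directions. The straight line over coded dose may account for this, since SR1 falls that are steep at low doses pull the shared intercept down and tilt the LGC006 line up. Fitted to the 0 nM and LGC006 arrays alone, 6 of the 15 slopes were above 0, with a median of −0.03. The fitted differences above may then be too large for the genes that fell, since all but HGD had a smaller measured difference at 1000 nM. For PRSS23 it was −3.08 where −3.56 was fitted. A biological opposite effect of LGC006 on single genes such as CTTNBP2, with measured differences from 0 nM of 0.41, 0.25 and 0.77, stays open.

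Mitosis genes had positive mean slopes with both compounds, which share the 0 nM array. Over the 7 treated arrays alone the lower of both mean slopes was 0.12 and the other 0.13, so a low 0 nM array is not needed for them. The standard errors over genes were 0.03 and 0.05. Standard errors over genes, here and below, treat genes read on the same arrays as independent and do not measure the spread between arrays. Among 10000 random lists matched on mean expression, the lower of the percentiles of the list's median slope was 98.67, which speaks against an intensity-dependent shift. Such lists do not allow for genes that vary together, so this shift is not excluded. Median centring lowers the SR1 slope of every gene by the same amount. The lower mean slope of the list given above therefore cannot decide on such a shift. With quantile normalization the mean slope went from 0.11 to 0.085 for SR1 and from 0.13 to 0.10 for LGC006. The list stayed called for both (camera adjusted p = 0.024 and 0.0027). The SR1 100 nM array, which had the highest ACTB ratio, is argued against as the cause. The mean LGC006 slope without it was 92.0% of that with it (SE over genes 4.1%), and its weight in the SR1 slope is 1.7% of the largest, too little to make that slope. A response to both compounds, an intensity-dependent shift, a property of the cultures that follows dose and chance within the estimated correlation stay open. Only the first was named by the design.

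CD34 and most other stem and progenitor genes had SR1 slopes above 0. Whether the whole list shifted, rather than CD34 alone, stays open. The list's median SR1 slope lay at percentile 99.91 of matched random lists, which does not allow for genes that vary together, and camera did not call the list (adjusted p = 0.17). A response to SR1, which the design names, was not tested further and stays open too.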

How the results depend on the processing

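The fit without the 0 nM array and with separate intercepts was chosen after seeing the data, and the other alternatives before. The 146 single-gene results gave 3420 values, many of them of results that had not passed. Only results that passed could lose a call or count as reversed, so 378 is not a share of all 3420. Of their values, none reversed and 378 lost the call. Of the values of results that had not passed, 21 gained a call and 62 of 25 results changed sign. Of the called lists, the neutrophil and promyelocyte list for LGC006 reversed, from a mean slope of −0.11 to 0.00082 (adjusted p = 0.74) without LGC006 1000 nM, and had −0.15 without LGC006 300 nM. The 16 genes of the SR1 trend kept their sign under each setting in which they were tested (12 of them with the filter at a mean of 7). The SR1 count of 16 became 0 with linear dose, 27 with dose ranks, 31 with the saturating and 0 with the step coding, 1 with each compound alone, 29 with median centring, 29 with quantile normalization, 3 with no filter, 32 with the filter at a mean of 7, 29 with every probe set on its own and 1 with treated arrays only. Leaving out 1 array gave 3 (without 0 nM) to 19 genes, with 8 without LGC006 30 nM and 8 without LGC006 300 nM. The difference count of 42 became 0 with linear dose, 75 with the saturating and 25 with the step coding, 1 with separate intercepts, 65 with quantile normalization, 4 with no filter, 74 with the filter at a mean of 7 and 0 with treated arrays only. Leaving out 1 array gave 2 (without LGC006 1000 nM) to 31 genes, with 24 without 0 nM and 21, 11 and 27 without SR1 30, 300 and 1000 nM, and 26 and 17 without LGC006 30 and 300 nM. The matched-dose count of 2 became 13 (1 higher, 12 lower) with median centring, 7 (1 higher, 6 lower) with quantile normalization, 0 with no filter, 26 with the filter at a mean of 7, 1 without an intensity trend, 6 with robust variances, 0 with the mean of the probe sets, 0 with every probe set on its own, 1 with no block for dose and 4 with 300 and 1000 nM only. Leaving out 1 array gave 0 (without either array at 300 or 1000 nM) to 4 (without either at 30 nM). LGC006 gave 0 genes under every setting. The 3 lists called for SR1 became 1 under each other coding of dose, separate intercepts, each compound alone, median centring, no intensity trend, the mean of the probe sets and treated arrays only, and 0 with an estimated correlation. Leaving out 1 array gave 1 (SR1 1000 nM or any LGC006 array) to 3 lists. The 4 lists for LGC006 became 1, shifted up, with separate intercepts and 1, also up, alone. With treated arrays only and separate intercepts they became 3 (1 up, 2 down). They became 0 with an estimated correlation and 0 with fry. With 1 array left out there were 0 (without LGC006 1000 nM) to 6, with 2 without SR1 30 nM. The 2 lists for the difference became 1 with treated arrays only, 0 with an estimated correlation and 5 with fry, and 2 to 3 with 1 array left out. Fewer tested genes under the stricter filter, more without a filter, and fewer arrays when some are left out are built into those settings, and for the others the cause was not tested. Fitting each compound alone gives no test of the difference. The share of probe sets at the floor, 33.2% to 34.6%, limits what can be said of dim genes such as CYP1A1.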

Other observations

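Of the listed genes that the account of the comparisons does not name, RRM2B and IER3 differed between the compounds. RRM2B, a p53-induced ribonucleotide reductase subunit, differed by −0.66 ± 0.10 (limma adjusted p = 0.037). IER3, an immediate early gene, passed as well (adjusted p = 0.043), but it lay below 31 with SR1 at each dose above 0 and at 33.1 with 1000 nM of LGC006, so it was at least 1.07-fold lower with SR1. In all, 7 of the 234 listed genes tested were lower and 1 (PECAM1) higher under SR1 than under LGC006. The BMP and TGF-beta target list held opposite movers, with SR1 slopes of 0.59 for ID1, −0.32 for ID2 and −0.85 for SMAD6. Adjusted over the list alone, 2 of its 6 members rose and 2 fell, while its camera adjusted p was 0.79. Of 11 interferon genes, 9 had SR1 slopes above 0, such as IFIT2 at 0.39, and RSAD2 had −0.76. The IFIT2 slope was 0.06 to 0.60 with single arrays left out. None of the 11 passed over all genes, and adjusted over the list alone 1 fell. CCL2, a monocyte chemokine, lay below 31 at each SR1 dose above 0.

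Lineage lists that were not called under SR1 were the erythroid (14 tested, median slope 0.04, camera adjusted p = 0.97), neutrophil and promyelocyte (13, −0.03, 0.22), monocyte (3, 0.13, 0.30), dendritic cell (4, −0.07, 0.17), B cell and early lymphoid (2, 0.07, 0.79), T and NK cell (1, 0.22, 0.38) and mast cell, basophil and eosinophil lists (7, 0.04, 0.58). DNA replication genes were measured in full, with 19 of 19 tested and a median slope of 0.02 (camera adjusted p = 0.97), beside the mitosis list's 0.08. The AHR complex (4 tested), NRF2 targets (8), p53 targets and CDK inhibitors (13), immediate early (8), heat shock (7), cholesterol synthesis (10), hypoxia and glycolysis (13), NF-kB (8), interferon (11), tryptophan and kynurenine (2) and adhesion (10) lists had median SR1 slopes from −0.09 to 0.08 and camera adjusted p-values from 0.30 to 0.97. Camera's direction was down for the erythroid, mast cell, DNA replication, p53, immediate early, heat shock and TGF-beta lists although their medians lay above 0, and none of these was called. The mean slope lay below 0 for the mast cell, p53, immediate early and TGF-beta lists.

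Slopes of SR1 and LGC006 correlated across genes at 0.32 (covariance 0.0091), where simulated arrays with no effect gave 0.52 (covariance 0.0088) in the same fit with its common intercept. The covariance exceeded the simulated one by 0.00030. With separate intercepts, where the 0 nM array enters the SR1 slope alone, the correlation was 0.064 (covariance 0.0023). These correlations are across genes, which are not independent replicates.

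Under the saturating coding of dose, genes that passed for SR1 besides those above included F2R at −0.61, MMP2 at −0.90, DMTN at −0.75, ETS2 at −0.60 and, among those that rose, TP53INP1 at 0.55 and DOCK5 at 0.44, chosen here after their values were seen. U2AF1 and ITGAL lay below the 0 nM array at each SR1 dose with no SR1 trend past the threshold, at log2 differences of −1.35, −1.20, −0.76 and −1.13 for U2AF1 and −0.71, −0.36, −0.90 and −0.83 for ITGAL.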
